A study of Mus musculus with 34 samples.

How the data were processed

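Liver RNA-seq was analysed from 34 mice in 4 groups set by the sex and age in the labels: 8 females and 9 males of 6 months, and 9 females and 8 males of 22 months. The labels name the stock UM-HET3 for all but 1 animal, replicate 4 of the 22-month males, whose strain label reads UM-HET4 and which stayed in its group. Replicate numbers follow the order of the samples and pair nothing.

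The deposited values are counts of reads per gene, 1 column per mouse, not normalized. Reads were aligned with STAR 2.6.0a to GRCm38 (mm10) and counted with HTSeq, per the submitters' processing notes. The HTSeq version, its strand setting and the gene annotation release are not given in the sources used here, so a gene and an overlapping or antisense partner may share reads. HTSeq counts a read only where it aligns to 1 place, and the table holds 5 summary entries that name no gene. These were left out of library sizes and tests. Of all reads in the table, a mean of 17.7% per library aligned to more than 1 place, 4.19% lay in no feature and 5.50% were ambiguous between genes. Members of near-identical families (Mup, Cyp2b, Cyp3a41, Cyp4a12, Sult2a, Ugt2b and immunoglobulin genes) lose or exchange such reads, and their single-gene values are uncertain. Of 53464 genes in the table, 53359 matched the GENCODE annotation by identifier, 105 did not, and 14551 had no read in any library. No pair of columns was identical, and the lowest chi-square per gene between any pair was 51.9, so every library was counted as a separate sample.

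Counts assigned to genes ranged from 42147628 to 49597855 per library, with a mean of 43409021 in the 6-month males, 46376136 in the 22-month males, 47559049 in the 6-month females and 47868757 in the 22-month females. Counts were simulated for each gene independently, from its mean over all libraries and with the same library sizes and spread. With 200 of 16579 genes changed, the test recovered 73% of 2-fold and 98% of 4-fold changes for sex at 6 months. It recovered 75% and 96% for sex at 22 months, 72% and 99% for age in males, 70% and 97% for age in females, and 68% and 87% for the interaction. Between 3.1% and 6% of the simulated calls were false. The simulation held no correlation between genes and no library that stood apart, so these rates need not hold for the real libraries.

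Genes were filtered with filterByExpr on the 4-group design, which left 16579. Counts were scaled with TMM and fitted in 1 model of all 34 libraries with edgeR 4.0.16 (estimateDisp, glmQLFit with robust estimation, glmQLFTest) in R 4.3.3. The contrasts were female minus male at each age, 22 minus 6 months in each sex, and the difference of the age changes (female minus male). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Standard errors of log2 fold changes were derived from the F statistic as the size of the change divided by the square root of F. Group levels are mean CPM, the counts of a gene scaled to a common library total, with the SD over mice. Where a group had no read of a gene, a fold was computed against a floor of 3 counts over the group, and with 1 to 3 reads as a ratio with its 95% counting interval; both cover counting error only.

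Before the data were examined, 34 gene lists were fixed from textbook knowledge, together with the tests and the rule for named genes. The lists cover sex-chromosome genes, sex-biased liver genes, cell type markers, and metabolic, stress and regulatory pathways. 1 gene, Egfr, stands on 2 lists. Each list was tested with camera in limma 3.58.1 on voom values with an inter-gene correlation estimated per list, two-sided, and adjusted over the lists within a contrast. The camera test with a preset correlation of 0.01 and fry, a rotation test of whether a list's genes move on balance one way, were alternatives. Members past the test were counted over all genes and adjusted over the list alone. A list score per mouse is the mean, over members, of log2 CPM centred on each gene. Scores were compared between ages within a sex by exact two-sided permutation tests, chosen after the data were seen, with adjustment over the 68 tests. Per contrast, the named genes are the 8 largest positive and 8 largest negative log2 fold changes among called genes with a mean CPM of at least 1 and a symbol that is not a clone, predicted or pseudogene name, up to 4 members of each list by smallest p, and the label check genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty.

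The alternatives fixed at the same time were relative log expression size factors, no filter on low counts, only the 2 groups of a contrast in the fit, libraries thinned to the smallest total, DESeq2 1.42.0, voom with sample quality weights, 5 surrogate variables from sva 3.50.0, and the fit without the library labelled UM-HET4. Alternatives chosen after seeing the data were the fit without 9 libraries whose summed CPM of pancreatic acinar genes was 10 or more, the log2 of that sum as a covariate, library size alone as the scaling, the percentage of reads in no feature as a covariate, the fit without the 2 libraries with the most genes detected, and each library left out in turn. Figures were drawn and tables joined in Python 3.11.15.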

Results

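Liver RNA was sequenced from UM-HET3 mice, a stock bred by intercrossing inbred strains so that each animal differs genetically from the others. The design asks how the liver transcriptome differs between females and males, at 6 and at 22 months of age, and how it differs between these ages in each sex. The 34 libraries held 42147628 to 49597855 reads assigned to genes. The sex labels matched the reads in 34 of 34 libraries. The lowest Xist level in a female was 267 CPM and the highest in a male 2.37 CPM. Reads of Y-linked genes numbered at least 4579 per male and at most 6 per female. The male with the most Xist, replicate 3 of the 6-month males, had 103 such reads, against 33 in the next, replicate 4. It also had the highest female-biased list score of its group (-1.91). The source of these reads was not tested.

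The first principal component of the 1000 most variable genes took 36.8% of the variance and separated all females from all males. The second took 15%. The median within-group SD of log2 CPM over genes was 0.26 in 6-month females, 0.22 in 6-month males, 0.32 in 22-month females and 0.28 in 22-month males. Transcripts of pancreatic acinar cells, such as trypsinogens and carboxypeptidases, summed to 10 CPM or more in 9 libraries: 1 of the 6-month females, 2 of the 6-month males, and 3 of each 22-month group. Their sums reached 4534 CPM in replicate 2 of the 6-month males and 3982 CPM in replicate 1 of the 6-month females. The other 25 libraries were below 10 CPM, the highest of them replicate 9 of the 6-month males at 7.73 CPM.

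**Figure D1:**
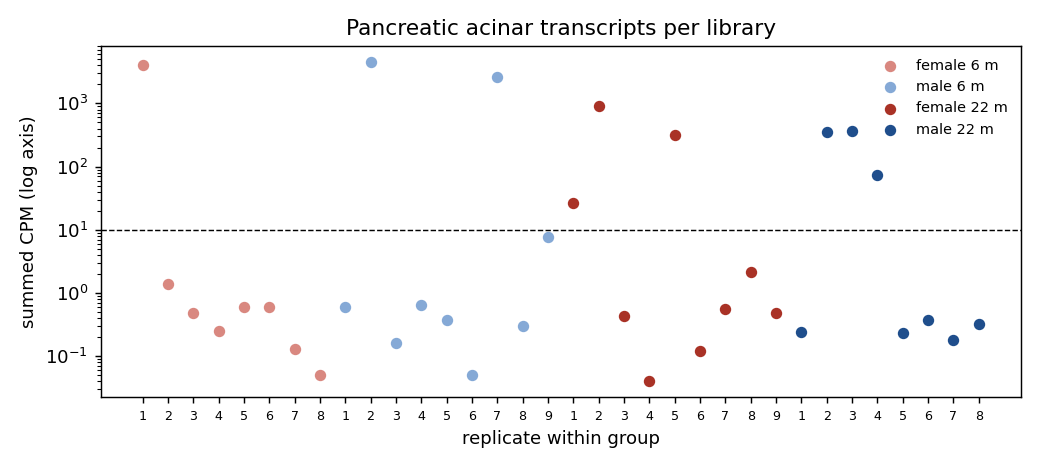
Summed CPM of pancreatic acinar genes (log axis) in each of the 34 libraries, 1 dot per library, coloured by group. The dashed line marks 10 CPM, which 9 libraries reached.

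At 6 months, cytochrome P450 genes were among those that differed between the sexes. Cyp2a4, a steroid-hydroxylating cytochrome P450 (chromosome 7, 26307169 to 26315088, GRCm38), stood at 604 ± 174 CPM in females (SD, n = 8) and 1.29 ± 1.30 CPM in males (n = 9), a log2 fold change of 8.87 ± 0.52 (SE) with an edgeR adjusted p of 2.51e-14. The male-biased Cyp4a12a, an arachidonic acid hydroxylase (chromosome 4, 115299046 to 115332815), stood at 0.62 ± 0.45 CPM in females and 587 ± 54.0 CPM in males, a log2 fold change of -9.88 ± 0.43 (adjusted p = 4.76e-18). In all, 2245 of 16579 genes were called, 1202 higher and 1043 lower in females, and 1089 of them changed by at least 1.5-fold.

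Of 32 genes on the female-biased liver list, 30 were higher in females at 6 months and 2 did not pass (30 adjusted over the list alone; median log2 fold change 7.06, camera adjusted p = 4.41e-07). The sulfotransferase Sult2a2 was at 93.3 ± 69.5 CPM in females and 0.040 ± 0.027 CPM in males. Its paralog Sult2a6 had no read in any male and was at least 841-fold higher in females, counted over the group. Values of single Sult2a genes are uncertain because such copies share reads. Of the 23 male-biased liver genes, 22 were lower in females and 1 did not pass (23 adjusted over the list alone; median -3.72, camera adjusted p = 6.36e-08). Gstp1, a glutathione transferase, had a log2 fold change of -3.27 ± 0.19 (adjusted p = 2.84e-15), and Susd4, a complement regulator, one of -4.02 ± 0.28 (adjusted p = 9.54e-13). All 4 Y-linked genes passed (4 adjusted over the list alone; camera adjusted p = 4.69e-08), and of 5 X-linked genes that escape inactivation 4 were higher in females and 1 did not pass (5 adjusted over the list alone; camera adjusted p = 0.0018), with Kdm6a at 0.69 ± 0.09 and Eif2s3x at 0.68 ± 0.11.

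Of 29 interferon-stimulated genes, 12 were higher in females at 6 months and 17 did not pass (20 adjusted over the list alone), with an adjusted p of 0.542 for the list with an estimated correlation and 1.95e-07 with the preset one. The count was 6 without replicate 3 and 5 without replicate 4 of the 6-month females, 7 without replicate 6 or 8 of the 6-month males, and 4 without the 9 libraries with acinar transcripts. Gbp3, an interferon-induced GTPase, was at 28.5 ± 25.9 CPM in females and 5.87 ± 3.56 CPM in males, a log2 fold change of 2.28 ± 0.49 (adjusted p = 0.0014), and Ddx60 at a log2 fold change of 1.18 ± 0.28 (adjusted p = 0.0036). Of 19 T and NK cell markers, 4 were higher and 15 did not pass (11 adjusted over the list alone; adjusted p = 0.553 with an estimated correlation). All 4 calls, those of Cd3d, Trbc1, Cxcr6 and Klrb1c, were lost without replicate 3 of the 6-month females, and 7 members were called without replicate 3 or 7 of the 6-month males. Among 14 NRF2 and glutathione genes, 2 were higher and 7 lower in females, and 5 did not pass (2 and 9 adjusted over the list alone; adjusted p = 0.388 with an estimated correlation). The exporter Abcc4 was higher, at 5.69 ± 2.69 CPM in females and 2.01 ± 0.37 CPM in males (adjusted p = 4.11e-06), and the glutathione transferase Gsta2 lower (-2.11 ± 0.37, adjusted p = 1.24e-04). Of 16 bile acid genes, 4 were higher and 2 lower, and 10 did not pass (5 and 2 adjusted over the list alone; adjusted p = 0.932 with an estimated correlation). The bile salt export pump Abcb11 was higher (0.68 ± 0.12, adjusted p = 1.23e-04). Of 12 growth hormone and IGF axis genes, 3 were higher and 9 did not pass (6 higher and 2 lower adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), and 5 were called without replicate 9 of the 6-month males. The prolactin receptor Prlr was higher (1.44 ± 0.17, adjusted p = 1.39e-07). Among 5 erythroid genes, Alas2, the erythroid enzyme of haem synthesis, was lower in females (-3.43 ± 0.27, adjusted p = 2.04e-11) and 4 did not pass (1 lower adjusted over the list alone; adjusted p = 0.229 with an estimated correlation). With library size alone as the scaling, 68.2% of calls were higher in females, against 53.5% with TMM, and with voom sample weights 4019 genes were called.

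**Figure D2:**
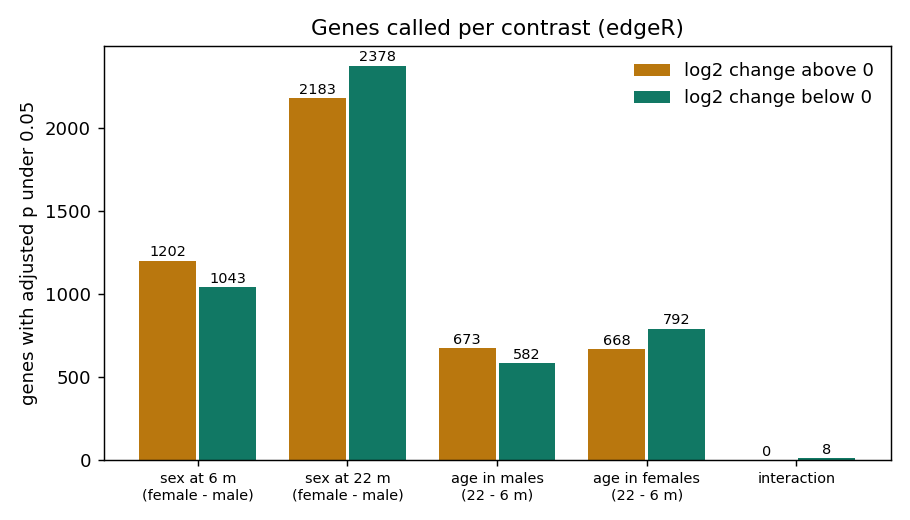
Genes with an edgeR adjusted p under 0.05 in each of the 5 contrasts, as bars split by the sign of the log2 change; the vertical axis counts genes and starts at 0. The sex contrasts hold 2245 calls at 6 months and 4561 at 22 months, the age contrasts 1255 in males and 1460 in females, and the interaction 8.

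At 22 months sex-biased cytochrome P450 genes differed again, and B cell and T cell markers were also called. Neither marker list passed by camera with an estimated correlation (adjusted p = 0.410 and 0.817). Cyp2a4 stood at 1054 ± 486 CPM in females (SD, n = 9) and 1.89 ± 1.15 CPM in males (n = 8), a log2 fold change of 9.12 ± 0.55 (SE; adjusted p = 5.19e-14). Cyp2d9, a steroid hydroxylase (chromosome 15, 82433437 to 82456845), stood at 25.6 ± 15.8 CPM in females and 1760 ± 233 CPM in males (-6.10 ± 0.38, adjusted p = 5.41e-14). Cd79a, a part of the B cell receptor (chromosome 7, 24897381 to 24902197), was at 7.20 ± 5.16 CPM in females and 1.88 ± 0.79 CPM in males (1.94 ± 0.46, adjusted p = 0.0019). In all, 4561 of 16579 genes were called, 2183 higher and 2378 lower in females, and 1694 of them changed by at least 1.5-fold.

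All 23 male-biased liver genes were lower in females at 22 months (23 adjusted over the list alone; median -4.44, camera adjusted p = 3.04e-06), and of 32 female-biased genes 28 were higher and 4 did not pass (29 adjusted over the list alone; median 5.51, camera adjusted p = 8.60e-06). Slco1a1, an organic anion transporter, stood at 3.66 ± 2.97 CPM in females and 258 ± 82.0 CPM in males. The Y-linked Kdm5d had no read in any 22-month female and was at least 2177-fold higher in males, counted over the group. All 4 Y-linked genes passed (4 adjusted over the list alone; camera adjusted p = 1.72e-06). Of 5 X-linked genes that escape inactivation, 2 were higher and 3 did not pass (3 adjusted over the list alone; adjusted p = 0.410 with an estimated correlation).

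Of 15 B and plasma cell markers, 10 were higher in females at 22 months and 5 did not pass (11 adjusted over the list alone; adjusted p = 0.410 with an estimated correlation). Ms4a1, the B cell antigen CD20, had a log2 fold change of 2.00 ± 0.48 (adjusted p = 0.0023). Of 19 T and NK cell markers, 11 were higher and 1 lower, and 7 did not pass (16 and 1 adjusted over the list alone; adjusted p = 0.817 with an estimated correlation), and the 12 calls became 7 without replicate 6 of the 22-month females. Cd2 was at 1.71 ± 0.43 (adjusted p = 0.0033). Of 21 cholesterol synthesis genes, 5 were higher and 16 did not pass (5 adjusted over the list alone; adjusted p = 0.930 with an estimated correlation), a count of 10 without replicate 1 and 3 without replicate 6 of the 22-month males. Their regulator Srebf2 was at 0.53 ± 0.12 (adjusted p = 0.0012). Of 21 fatty acid oxidation and PPARA target genes, 6 were higher and 1 lower, and 14 did not pass (6 and 1 adjusted over the list alone; adjusted p = 0.930 with an estimated correlation). The pantetheinase Vnn1 was higher (1.95 ± 0.40, adjusted p = 4.51e-04) and so was the fatty acid transporter Cd36 (1.80 ± 0.43, adjusted p = 0.0024). Of 15 fatty acid synthesis genes, 2 were higher and 2 lower, and 11 did not pass (2 and 2 adjusted over the list alone; adjusted p = 0.930 with an estimated correlation). The lipase Pnpla3 was at 1.64 ± 0.30 (adjusted p = 1.32e-04) and the desaturase Scd1 at -1.84 ± 0.49 (adjusted p = 0.0058), a call lost with voom sample weights and without the 9 libraries with acinar transcripts. Of 16 unfolded protein response genes, 6 were lower and 10 did not pass (7 adjusted over the list alone; adjusted p = 0.846 with an estimated correlation). Herpud1 was at -0.66 ± 0.12 (adjusted p = 1.28e-04). Among 14 NRF2 and glutathione genes, 2 were higher and 8 lower, and 4 did not pass (2 and 8 adjusted over the list alone; adjusted p = 0.817 with an estimated correlation). Interferon-stimulated genes at this age were higher for 6 of 29 and 23 did not pass (6 adjusted over the list alone; adjusted p = 0.930 with an estimated correlation). Without the 9 libraries with acinar transcripts the called members were 1 of the cholesterol synthesis, 3 of the fatty acid oxidation and 2 of the fatty acid synthesis genes, and 1 of the X-linked genes.

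The sexes differed in the same direction at both ages for 1395 of the 1397 genes called at both, 676 higher and 719 lower in females, against 158.3 and 149.6 for independent lists. The libraries of the ages are separate, so no control is shared. Both contrasts did use 1 estimate of each gene's spread, so the lists are not independent. The values for independent lists may thus be too low. Across genes, which are not independent replicates, the fold changes at 6 and 22 months had a Pearson correlation of 0.84 and a Spearman correlation of 0.59.

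In males, Lcn2, Apcs and Cdkn1a were among the genes higher at 22 than at 6 months, and Ugt2b38, Mup18 and Krt23 among those lower. Lcn2, an iron-binding acute phase protein (chromosome 2, 32384633 to 32388252), rose from 7.07 ± 4.12 CPM (SD, n = 9) to 138 ± 173 CPM (n = 8), a log2 fold change of 4.28 ± 0.91 (SE; adjusted p = 0.0031), and was 3.53 without replicate 6 of the 22-month males. Apcs, serum amyloid P component, rose from 95.6 ± 28.1 to 339 ± 193 CPM (1.83 ± 0.30, adjusted p = 1.96e-04) and was above every 6-month male in 8 of 8 mice. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 3.10 ± 2.98 to 26.7 ± 30.4 CPM (3.11 ± 0.72, adjusted p = 0.0065), above the 6-month median in 8 of 8 mice. The rise was uneven and the groups overlapped. Replicates 7 and 3 of the 22-month males were at 78.4 and 68.6 CPM and replicate 1 at 3.85 CPM. The highest 6-month male, replicate 9, was at 10.65 CPM. In all, 1255 of 16579 genes were called, 673 higher and 582 lower at 22 months, and 538 of them changed by at least 1.5-fold.

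Of 9 neutrophil markers, 6 rose in males and 3 did not pass (9 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation). S100a9 rose from 0.64 ± 0.22 to 2.48 ± 1.72 CPM (1.95 ± 0.36, adjusted p = 7.94e-04). Of 14 p53 target and senescence genes, 7 rose and 7 did not pass (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.2004 with an estimated correlation), a count of 3 without replicate 3 and 4 without replicate 6 of the 22-month males. Cdkn2a, the locus of the inhibitor p16 (chromosome 4, 89274471 to 89294653), rose from 0.098 ± 0.070 to 0.45 ± 0.20 CPM (2.18 ± 0.47, adjusted p = 0.0037), and Eda2r, a p53 target receptor, by 1.97 ± 0.43 (adjusted p = 0.0038). Of 19 acute phase proteins, 8 rose and 11 did not pass (13 adjusted over the list alone; adjusted p = 0.331 with an estimated correlation). The count was 4 without replicate 6 of the 22-month males, and 5 without replicate 8 of them or 1, 3, 4, 6 or 7 of the 6-month males. Of 12 monocyte and lipid-associated macrophage markers, 4 rose and 8 did not pass (7 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation). The count was 1 without replicate 2 of the 22-month males, which ended the calls of Gpnmb, Mmp12 and Ms4a7, and 2 without replicate 8 of them or 1, 3, 4, 6 or 7 of the 6-month males. Cd9 was at 1.09 ± 0.17 (adjusted p = 1.34e-04). Of 15 B and plasma cell markers, 5 rose, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation). Igha, the immunoglobulin A heavy chain, rose by 2.05 ± 0.49 (adjusted p = 0.008) and Derl3, an endoplasmic reticulum degradation factor, fell by 2.28 on the log2 scale (SE 0.52, adjusted p = 0.0059).

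Of 32 female-biased liver genes, 4 rose in males with age and 28 did not pass (6 adjusted over the list alone; adjusted p = 0.643 with an estimated correlation), a count of 8 without replicate 3 of the 6-month males and 2 without replicate 3 of the 22-month males. Cyp2b9 rose from 1.41 ± 1.89 to 15.6 ± 15.98 CPM (3.46 ± 0.64, adjusted p = 7.75e-04), a change of 4.22 without replicate 3 of the 6-month males. Of 23 male-biased genes, 4 fell and 19 did not pass (7 adjusted over the list alone; adjusted p = 0.0999 with an estimated correlation). The glucuronosyltransferase Ugt2b38 fell from 6.35 ± 3.87 to 0.50 ± 0.39 CPM (-3.65 ± 0.51, adjusted p = 2.12e-05) and Cyp4a12b from 68.5 ± 16.2 to 24.5 ± 15.5 CPM (-1.48 ± 0.23, adjusted p = 1.38e-04). Mup18 fell by 3.85 on the log2 scale (SE 0.70, adjusted p = 6.66e-04), a value made uncertain by reads shared among Mup copies. Krt23, a keratin on the cholangiocyte list, fell from 12.2 ± 4.36 to 1.10 ± 0.94 CPM (-3.48 ± 0.58, adjusted p = 2.96e-04), below every 6-month male in 8 of 8 mice. The other 10 cholangiocyte genes did not pass (1 lower adjusted over the list alone; adjusted p = 0.885 with an estimated correlation), and 2 members were called without replicate 2 of the 6-month males. Nebl, an actin-binding protein, rose from 0.35 ± 0.10 to 2.98 ± 1.02 CPM (3.08 ± 0.30, adjusted p = 6.64e-08).

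Of 18 circadian clock genes, 3 rose and 2 fell in males and 13 did not pass (4 and 9 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation), and 9 were called without replicate 1 of the 22-month males. Npas2 rose by 2.74 ± 0.56 (adjusted p = 0.002) and Arntl by 1.95 ± 0.43 (adjusted p = 0.0044), both activators of the clock, while the repressor Cry2 changed by -0.56 ± 0.10 (adjusted p = 7.56e-04). The time of day of collection is not given in the sources used here, for either sex or age. Of 21 fatty acid oxidation and PPARA target genes, 4 fell and 17 did not pass (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.311 with an estimated correlation). The count was 2, with Hadha and Hadhb lost, without replicate 7 of the 6-month males or 2, 3 or 6 of the 22-month males. The fatty acid hydroxylase Cyp4a10 fell from 4392 ± 532 to 2218 ± 686 CPM (-0.99 ± 0.19, adjusted p = 0.0014). Of 9 heat shock genes, 4 fell and 5 did not pass (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.291 with an estimated correlation). The count was 1 without replicate 4 of the 6-month males or 2, 3, 7 or 8 of the 22-month males, and 2 without replicates 3, 5, 6, 7 or 8 of the 6-month or 1 or 5 of the 22-month males. Hspd1 was at -0.31 ± 0.06 (adjusted p = 0.0016). By camera, 0 of 34 lists passed in males, 4 had an unadjusted p under 0.05, 17 passed with the preset correlation and 11 by fry.

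Without the 9 libraries with acinar transcripts, 361 genes were called in males, and the calls of Cdkn1a, Cdkn2a, Arntl, Derl3 and Cyp2b9 were lost in that fit of 7 and 5 males. Of the listed members, 2 neutrophil, 2 p53 and senescence, 2 acute phase, 1 monocyte and macrophage, 0 female-biased, 2 male-biased, 2 circadian, 1 fatty acid oxidation and 1 heat shock gene were then called with the same sign. With library size alone as the scaling 81.4% of calls were higher at 22 months, against 53.6% with TMM.

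In females, 13 of 15 B and plasma cell markers were higher at 22 than at 6 months and 11 of 23 male-biased liver genes lower (camera adjusted p = 0.0446 and 0.0491). These list calls were lost in 8 and 25 of 34 fits without 1 library. Igha (chromosome 12, 113254830 to 113260236) rose from 1.25 ± 0.85 CPM (SD, n = 8) to 12.6 ± 10.97 CPM (n = 9), a log2 fold change of 3.33 ± 0.52 (SE; adjusted p = 1.63e-04), and was above every 6-month female in 9 of 9 mice. Slco1a1 (chromosome 6, 141907282 to 141946962) fell from 61.2 ± 38.0 to 3.66 ± 2.97 CPM (-4.06 ± 0.40, adjusted p = 1.72e-07), and Mup7 from 10.3 ± 7.63 to 0.58 ± 0.46 CPM (-4.15 ± 0.49, adjusted p = 4.23e-06). The oestrogen sulfotransferase Sult1e1 rose from 2.13 ± 1.62 to 20.8 ± 15.3 CPM (3.29 ± 0.56, adjusted p = 4.29e-04). In all, 1460 of 16579 genes were called, 668 higher and 792 lower at 22 months, and 637 of them changed by at least 1.5-fold.

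**Figure D3:**
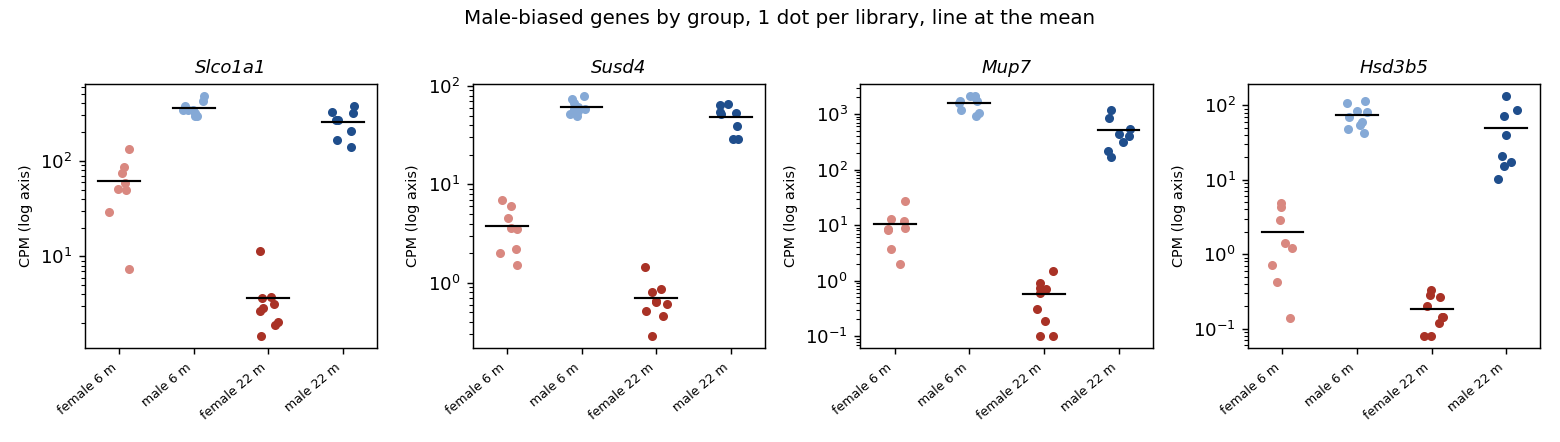
CPM (log axis) of Slco1a1, Susd4, Mup7 and Hsd3b5 in each group, 1 dot per library and a line at the group mean. Mean Slco1a1 was 61.2 CPM in 6-month and 3.66 CPM in 22-month females, and 357 and 258 CPM in males.

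Of 15 B and plasma cell markers, 13 rose in females and 2 did not pass (14 higher and 1 lower adjusted over the list alone; median 2.32, camera adjusted p = 0.0446). Igkc, the kappa light chain constant region, rose from 6.20 ± 4.42 to 42.6 ± 17.6 CPM (2.78 ± 0.49, adjusted p = 6.19e-04), and Ighm, the immunoglobulin M heavy chain, from 12.7 ± 7.91 to 81.1 ± 34.1 CPM (2.67 ± 0.48, adjusted p = 7.14e-04). The mean list score was 2.17 higher at 22 months in females, with 9 of 9 mice above every 6-month female (exact permutation p = 4.11e-05, adjusted p = 9.32e-04), and 1.30 higher in males (exact permutation p = 0.004, adjusted p = 0.034). In males 8 of 8 mice were above the 6-month median but 1 of 8 above every 6-month male, of which replicate 7 stood apart at a score of 0.86. Of 23 male-biased liver genes, 11 fell and 12 did not pass (12 adjusted over the list alone; median -1.13, camera adjusted p = 0.0491). Their mean score was 1.27 lower in 22-month females, with 9 of 9 mice below every 6-month female (difference -1.27, exact permutation p = 4.11e-05, adjusted p = 9.32e-04). In males it was 0.87 lower at 22 months, with 8 of 8 mice below the 6-month median and 7 of 8 below every 6-month male (difference -0.87, exact permutation p = 1.645e-04, adjusted p = 0.0028). By the same permutation tests, the p53 and senescence score was 0.74 higher at 22 months in males (adjusted p = 9.325e-04) and 0.55 in females (adjusted p = 0.0073). The neutrophil score was 1.28 higher in males (adjusted p = 0.0089) and 1.21 in females (adjusted p = 0.0243). In males the monocyte and macrophage score was 0.69 higher (adjusted p = 0.0462) and the heat shock score changed by -0.48 (adjusted p = 0.0355). The monocyte and macrophage score was also 0.69 higher in females but did not pass (adjusted p = 0.0525). There 9 of 9 mice were above the 6-month median and 1 of 9 above every 6-month female. No difference between the sexes is shown for that score. No other list score passed in either sex. Hsd3b5, a male-biased steroid-metabolising enzyme, fell from 1.98 ± 1.80 to 0.18 ± 0.093 CPM (-3.42 ± 0.63, adjusted p = 8.64e-04), a call lost with voom sample weights. Of 32 female-biased genes, 2 rose and 30 did not pass (1 adjusted over the list alone; adjusted p = 0.984 with an estimated correlation), and 1 was left in 14 of 34 fits without 1 library, those without replicates 1, 2, 5, 6 or 7 of the 6-month females, 1, 3, 4, 6, 8 or 9 of the 6-month males, or 1, 5 or 8 of the 22-month females.

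**Figure D4:**
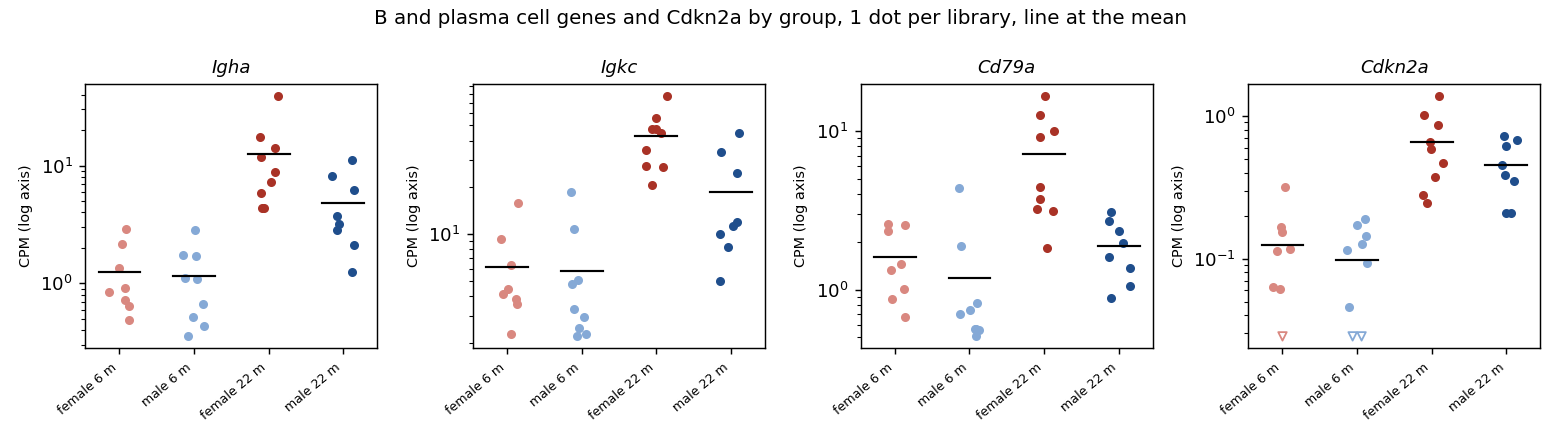
CPM (log axis) of Igha, Igkc, Cd79a and Cdkn2a in each group, 1 dot per library and a line at the group mean; open triangles below the axis range of the other points stand for libraries with no read. Igha averaged 1.25 CPM in 6-month and 12.6 CPM in 22-month females, and Cdkn2a 0.12 and 0.65 CPM.

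Of 19 T and NK cell markers, 3 rose and 1 fell in females and 15 did not pass (4 and 1 adjusted over the list alone; adjusted p = 0.622 with an estimated correlation), and 2 of the 4 calls were left without replicate 4 of the 6-month females. Cd8b1 was at 2.29 ± 0.45 (adjusted p = 0.0016) and Cd2 at 1.91 ± 0.43 (adjusted p = 0.0057). Of 9 neutrophil markers, 5 rose and 4 did not pass (7 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation). The count was 2 without replicate 5 or 8 and 3 without replicate 2, 4 or 7 of the 6-month females, and 3 without replicate 2, 3, 4, 8 or 9 of the 22-month females. S100a9 was at 1.37 ± 0.36 (adjusted p = 0.0157). Of 14 p53 target and senescence genes, 3 rose and 11 did not pass (4 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation). Cdkn2a rose from 0.12 ± 0.095 to 0.65 ± 0.38 CPM (2.36 ± 0.46, adjusted p = 0.0015), and Phlda3 by 1.31 ± 0.31 (adjusted p = 0.0086). Cdkn1a was at 19.5 ± 27.5 and 18.5 ± 9.97 CPM (-0.08 ± 0.67, adjusted p = 0.958). Replicate 2 of the 6-month females was at 82.4 CPM, and without it the change was 0.80 (adjusted p = 0.4715), so no direction is shown. The change was 1.42 with voom sample weights (adjusted p = 0.1296) and 1.08 with surrogate variables (adjusted p = 0.196). Of 10 periportal hepatocyte genes, 3 fell and 7 did not pass (3 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation). Cyp2f2 fell from 562 ± 81.0 to 290 ± 114 CPM (-0.96 ± 0.16, adjusted p = 3.95e-04). Of 10 pericentral genes, 2 fell and 8 did not pass (3 adjusted over the list alone; adjusted p = 0.622 with an estimated correlation), and 1 was left without replicate 4 or 8 of the 6-month or 3 or 8 of the 22-month females. Cyp1a2 was at -0.74 ± 0.19 (adjusted p = 0.0162), a call lost with only the 2 groups in the fit. Of 14 NRF2 and glutathione genes, 3 rose and 11 did not pass (6 adjusted over the list alone; adjusted p = 0.547 with an estimated correlation), a count of 5 without replicate 4 of the 22-month females. Abcc4 was at 0.94 ± 0.21 (adjusted p = 0.0051). Of 16 bile acid genes, 2 fell and 14 did not pass (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), and 5 were called without replicate 1 and 4 without replicate 4 of the 22-month females. Cyp27a1, a sterol hydroxylase, was at -0.61 ± 0.13 (adjusted p = 0.0034). Circadian clock genes fell for 2 of 18 and 16 did not pass (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.547 with an estimated correlation). The circadian score changed with age by -0.29 in females and -0.31 in males (exact permutation tests, adjusted p = 0.0525 for each). An unrecorded time of collection thus bears on both sexes. The cell adhesion gene Cdh1 fell from 12.1 ± 6.30 to 2.63 ± 1.74 CPM (-2.20 ± 0.35, adjusted p = 1.81e-04).

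The camera call of the male-biased list held in 9 of 34 fits without 1 library, those without replicates 4, 5, 7 or 8 of the 6-month females, 2 or 9 of the 6-month males, or 1, 2 or 5 of the 22-month males. Its adjusted p reached 0.133 without replicate 4 of the 22-month females. The call of the B and plasma list held in 26 such fits. It was lost without replicate 2 of the 6-month females, 3 or 4 of the 6-month males, 1, 4, 6 or 9 of the 22-month females or 4 of the 22-month males (adjusted p up to 0.0647, without replicate 6). Without the 9 libraries with acinar transcripts 877 genes were called, with 7 male-biased, 2 T and NK, 1 NRF2 and 6 bile acid members among them, and the calls of Abcc4 and Phlda3 were lost, with only the 2 groups in the fit 575, and with library size alone 66.6% of calls were higher, against 45.8% with TMM.

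The age changes of males and females, measured in separate mice, shared 335 called genes, of which 332 moved the same way: 179 higher and 153 lower, against 27.1 and 27.8 for independent lists. Here too the contrasts used 1 estimate of each gene's spread, so the values for independent lists may be too low. The mouse numbers in the labels do not overlap between the ages, and the labels name no batch. Agreement between the sexes therefore cannot tell age from a batch that follows it. Across genes the fold changes had a Pearson correlation of 0.58 and a Spearman correlation of 0.41. S100a9, Cdkn2a, Igha, Lcn2 and Apcs were called higher in both sexes, the call of Lcn2 in females being lost without replicate 1 of the 22-month females (adjusted p = 0.0516) and that of Apcs in females without replicate 6 of the 22-month females (adjusted p = 0.0621). Both calls in females were also lost with only the 2 groups in the fit, with voom sample weights and without the 9 libraries with acinar transcripts, and that of Apcs with no filter on low counts. The test of the difference between the age changes called 8 genes, all with a more negative change in females. Regroupings of the same libraries could not decide whether chance gave this count, so chance is not excluded.

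**Figure D5:**
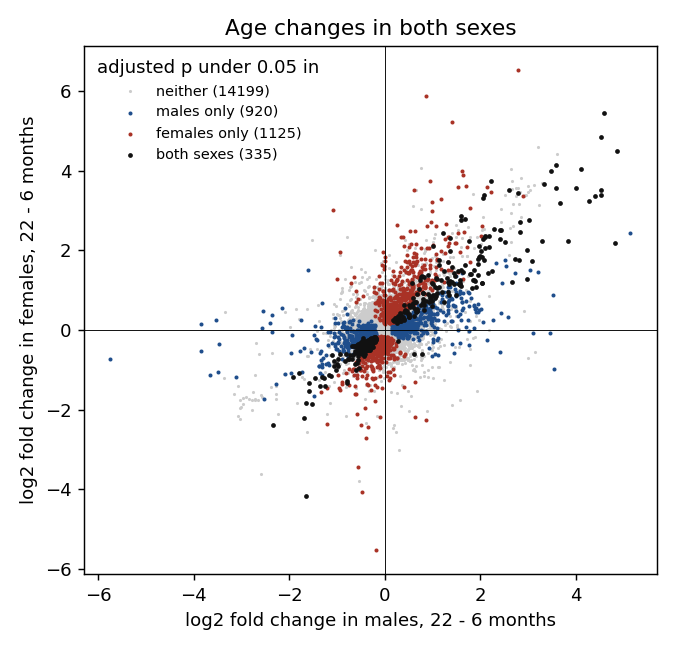
Log2 fold change from 6 to 22 months in males (horizontal) and females (vertical) for each of 16579 genes, coloured by the sexes in which the edgeR adjusted p was under 0.05. Of 335 genes called in both, 332 lie in the quadrants of equal sign.

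Slco1a1 fell by 4.06 on the log2 scale in females and stood at -0.47 ± 0.35 in males (adjusted p = 0.476), a difference of -3.59 ± 0.51 (adjusted p = 5.17e-04). Susd4 differed by -2.08 ± 0.36 (adjusted p = 0.0118). Myef2, a transcriptional repressor (chromosome 2, 125084628 to 125123661), fell in females from 2.09 ± 0.33 to 1.36 ± 0.35 CPM and rose in males from 3.63 ± 0.51 to 6.21 ± 1.24 CPM, a difference of -1.39 ± 0.19 (adjusted p = 4.86e-04). Acnat2, an acyltransferase, rose in males from 31.8 ± 16.6 to 103 ± 32.1 CPM and stood at 127 ± 33.0 and 135 ± 21.8 CPM in females (-1.61 ± 0.31, adjusted p = 0.0317). Dmrta1 rose in both sexes, by 2.98 ± 0.25 in males and 1.28 ± 0.24 in females (-1.70 ± 0.33, adjusted p = 0.0337). Dpy19l1 differed by -0.86 ± 0.17 (adjusted p = 0.0468). Gm379 (-4.52 ± 0.82, adjusted p = 0.0163) and Nup62cl (-3.12 ± 0.62, adjusted p = 0.0422) fall outside the rule for named genes and were chosen after their values were seen. Myef2, Slco1a1 and Susd4 kept their calls whichever library was left out, and Myef2 alone of the 6 genes named by rule kept its call without the 9 libraries with acinar transcripts. The call of Acnat2 was lost without replicate 4, 7 or 8 of the 6-month males, 3, 6 or 7 of the 22-month males or 5 of the 22-month females (adjusted p up to 0.0657). Dmrta1 lost its call in 12 of 34 such fits (adjusted p up to 0.0732), those without replicate 6 or 7 of the 6-month females, 2, 4, 7 or 8 of the 6-month males, 2 or 5 of the 22-month females or 3, 5, 6 or 7 of the 22-month males. Dpy19l1 lost its call in 23 (adjusted p up to 0.0966) and kept it only without replicate 4, 5 or 8 of the 6-month females, 5 of the 6-month males, 3, 4, 6 or 9 of the 22-month females or 1, 2 or 8 of the 22-month males. The count of 8 calls ran from 4 without replicate 4, 7 or 8 of the 6-month males or 7 of the 22-month males to 66 without replicate 4 of the 22-month females. DESeq2 called 112 genes. By camera 0 of 34 lists passed in the interaction, with 2 at an unadjusted p under 0.05, 10 with the preset correlation and 0 by fry.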

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

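The tests chosen only after the result was seen were those of Mup copies, of hepatocyte share, of leukocyte share, of selection by a low level and of how far other groupings follow the real one, and every fit without libraries with acinar transcripts or with the share of reads in no feature.

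Male-biased liver genes were lower at 22 than at 6 months in females, with a median log2 change of -1.13 over 23 genes. Reads shared among Mup copies are argued against, since members that are not Mup genes had a median of -0.94 (quartiles -1.63 and -0.49). Pancreas carried over into some libraries is argued against by a median of -1.03 without the 9 libraries (quartiles -1.57 and -0.56), although the camera call was then lost (adjusted p = 0.12). A lower share of hepatocytes would lower other hepatocyte genes as much, and is argued against as the whole cause by medians of 0.05 for female-biased genes (quartiles -0.38 and 0.72), -0.42 for periportal (-0.61 and -0.25), -0.26 for pericentral (-0.39 and 0.08) and -0.25 for bile acid genes (-0.34 and -0.03). A smaller contribution of that kind and an effect of age itself stay open and untested, and the list's call changed with single libraries.

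B and plasma cell markers were higher at 22 than at 6 months in females, with a median log2 change of 2.32. Lymphoid tissue carried over with pancreas is argued against by a median of 2.15 without the 9 libraries (quartiles 1.87 and 2.58). A rise of all leukocytes by the same amount is argued against, since the B and plasma score minus the T and NK score was 1.49 higher at 22 months (exact permutation p = 0.0001645), minus the Kupffer score 2.06, minus the monocyte and macrophage score 1.48 (exact permutation p = 8.227e-05 for each) and minus the neutrophil score 0.96 (exact permutation p = 0.0139). Lymphoid tissue without pancreas and an age effect stay open and untested.

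Of 179 genes higher at 22 months in both sexes, 64 had a mean under 0.5 CPM at 6 months, against 1 of 153 genes lower in both, and 15.5% of tested genes were as low; 12 of the 64 are immunoglobulin genes, and S100a8 and Cxcr2 are on the neutrophil list. Deeper sequencing of the older libraries is argued against, since 81.2% of the 64 kept both calls in thinned libraries, and so is genomic DNA or unspliced RNA, with 92.2% kept when the share of reads in no feature was a covariate. Selection by a low 6-month level is argued against too: among 46 genes called in both sexes and low by their mean over all libraries, 95.7% were higher (exact binomial interval 85.2 to 99.5), against 53.9% of all genes called in both. That interval takes genes as independent. Immunoglobulin and olfactory receptor genes are among the 64 and may move together, so the interval may be too narrow. Without the 9 libraries with acinar transcripts 35.9% kept both calls, in a fit with fewer mice. Random removals of libraries were not scored for these 64 genes, so the loss cannot be assigned to fewer mice or to those libraries. Tissue carried over with pancreas is therefore not argued against and stays open. More leukocytes in older livers, for those 14 genes at least, and an effect of age stay open and untested.

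Of 305 groups of values tested for a sample far from the others, 17 had one (5.6%), and chance gives about 1 in 20. Among list scores these were B and plasma cell markers in replicate 7 of the 6-month males (0.86), liver endothelial markers in replicate 2 of the 6-month males (0.34) and replicate 4 of the 22-month males (-1.39), acinar genes in replicate 1 of the 6-month females (10), fatty acid synthesis in replicate 2 (-0.79) and acute phase proteins in replicate 3 (0.62) of the 6-month females. Among log2 CPM values in 6-month mice they were Cyp2b13 (5.93) and Ccr3 (-3.49) in female replicate 2, Ighg2b (1.2) and Orm2 (4.93) in female replicate 3, Sult2a3 in male replicate 6 (-4.47) and Sult2a5 in male replicate 3 (-3.46). In 22-month females they were Cyp4a12a (-0.02), Cyp3a41b (3.12) and Slco1a1 (3.50) in replicate 9, Obp2a in replicate 7 (1.39) and Eif4ebp3 in replicate 1 (2.19). Over all 6-month males Sult2a3 had 1 read and Sult2a5 had 3, with every other male at the floor. The rate of 1 in 20 does not hold for these flags.

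The test of the difference between the age changes, for whose count chance cannot be excluded, called Myef2 (-1.39), Slco1a1 (-3.59), Susd4 (-2.08), Gm379 (-4.52), Acnat2 (-1.61), Dmrta1 (-1.70), Nup62cl (-3.12) and Dpy19l1 (-0.86), female minus male on the log2 scale. Reads aligned to more than 1 place, outside the gene counts, averaged 17.7% per library. The male mean exceeded the female one by 3.24 percentage points (17 mice of each sex, permutation p = 1e-05, the smallest 100000 resamples can give), by 4.39 at 6 months (exact permutation p = 4.11e-05) and by 1.91 at 22 months (exact permutation p = 0.0197).

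Calls were counted in 100 groupings of the same libraries, the real one included. For sex at 6 months 1 grouping gave as many calls (real 2245, highest other 1), for sex at 22 months 1 (4561, 1666), for age in males 1 (1255, 61) and for age in females 1 (1460, 307). In each, the real grouping alone reached its count, the smallest share that 100 groupings can show. Chance is therefore unlikely for these counts. For the interaction 6 groupings gave as many (real 8, highest other 622). These shuffled age within each sex, which also broke up the age change that the sexes share. That setting differs from the data, so the share of groupings cannot decide, and chance is not excluded. The grouping with 622 calls, far above the real count, may reflect a structure of the samples, which was not tested. It kept 6 of the 9 females and 2 of the 8 males of 22 months in their age group, so a remainder of the real age difference may enter it. Over the 99 other groupings the Spearman correlation of calls with such imbalance was 0.19 (asymptotic two-sided p = 0.0587), which leaves this open. For sex at 22 months that correlation was 0.40 (p = 4.169e-05, same test) and for age in females 0.23 (p = 0.02). It was 0.06 for sex at 6 months and 0.09 for age in males. These p values take the groupings as independent, though all redraw the same libraries, and do not measure spread between mice. Any call at all was made in 22 of the 99 groupings for sex at 22 months. For age in females it was 12 and for the interaction 10, so most values were tied. The number of groupings was raised from 50 to 100 after a first count, in which 3 gave as many.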

How the results depend on the processing

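The tests chosen only after the result was seen were the fits without 9 libraries with acinar transcripts, without the 2 libraries with the most genes detected, with the acinar sum or the share of reads in no feature as a covariate, with library size alone, and without each library in turn. No list call or named call took the opposite sign in the settings run or without 1 library, but the larger side of the calls turned in some. The share higher for sex at 6 months (53.5%) was 49.9% with only the 2 groups in the fit, 48.3% without the UM-HET4 library and 47.1% without the 9 libraries, and under 50% in 15 of 34 fits without 1 library. For sex at 22 months (47.9%) it was 51.5% in thinned libraries, 51% with surrogate variables and above 50% in 2 such fits. For age in males (53.6%) it was 49.2% with only the 2 groups, 48.2% with voom weights and under 50% in 1 such fit. For age in females (45.8%) it was 51.5% with only the 2 groups, 50.6% in thinned libraries, 51% with surrogate variables, 66.6% with library size alone and above 50% in 1 such fit. Among all genes, 1 of the 1460 called for age in females had a change of opposite sign without the 9 libraries. Counts stayed within 1.5 times the reported one in 12 of 13 settings for sex at 6 months, 13 of 13 for sex at 22 months, 9 of 13 for age in males, 10 of 13 for age in females and 8 of 12 for the interaction. For sex at 6 months, voom with sample weights gave 4019. For age in males, no filter gave 757, voom with weights 2120, surrogate variables 2150 and removal of the 9 libraries 361. For age in females, only the 2 groups in the fit gave 575, removal of the 9 libraries 877 and removal of the 2 libraries with the most genes detected 882. For the interaction, DESeq2 gave 112, surrogate variables 79, the no-feature share 15 and removal of the 9 libraries 2. Removals left fewer samples, and the cause of the other shifts was not tested. Over the 34 lists and 5 contrasts, 9 calls became 63 with a preset correlation and 41 by fry. Of 89 pairs of a list and a contrast with a called member, the count of called members moved by over 1.5 times in 70 under some setting (45 without the 9 libraries, 35 with no filter, 31 with voom weights, 28 with only the 2 groups in the fit) and in 47 without some library. The adjusted p of the male-biased list in females was 0.0618 without the UM-HET4 library, 0.0522 with relative log expression, 0.15 with voom weights and 0.12 without the 9 libraries, and that of the B and plasma list 0.0542 without the UM-HET4 library and 0.0615 with voom weights. Leaving out 1 library gave 1804 to 2355, 3920 to 5070, 863 to 1338, 991 to 2093 and 4 to 66 calls in the order above, with list p values from 0.0244 to 0.133 (male-biased) and 0.0174 to 0.0647 (B and plasma). The interaction count was 66, 26 and 15 without replicates 4, 9 and 6 of the 22-month females, 14 without replicate 5 of the 6-month males, 13 without replicate 2 of the 22-month males, 4 without replicates 4, 7 or 8 of the 6-month or 7 of the 22-month males, and 5 without replicate 2 of the 6-month males, 7 of the 6-month females, 5 of the 22-month females, or 3 or 6 of the 22-month males. The share of calls higher with library size alone was 68.2% for sex at 6 months and 81.4% for age in males.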

Other observations

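The tests chosen only after the result was seen were both tests of sex-biased genes and the random removal of libraries. Olfr701 and Olfr1030, olfactory receptor genes on different chromosomes, rose with age in both sexes and were chosen after their values were seen. Olfr701 (chromosome 7, 106814129 to 106821472, GRCm38) rose from 0.10 ± 0.11 to 1.64 ± 0.94 CPM in males (log2 fold change 4.01 ± 0.56, edgeR adjusted p = 1.90e-05) and from 0.070 ± 0.072 to 0.85 ± 0.49 CPM in females (3.57 ± 0.60, adjusted p = 3.25e-04). Olfr1030 (chromosome 2, 85979276 to 85988294) rose by 3.33 ± 0.51 in males (adjusted p = 8.61e-05) and 3.68 ± 0.52 in females (adjusted p = 3.36e-05). Neighbouring or overlapping genes can share reads, so these values are uncertain.

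Of 16 antigen presentation genes, 3 were higher in females at 6 months and 13 did not pass (3 adjusted over the list alone, adjusted p = 0.886 with an estimated correlation). Of these calls 1 was left without replicate 3 of the 6-month females, which ended those of Psmb9 and Tapbp, and 0 without the 9 libraries with acinar transcripts. Of 8 oncofetal liver genes, 2 rose with age in males and 6 did not pass (2 adjusted over the list alone, adjusted p = 0.833 with an estimated correlation), with Afp at 0.87 ± 0.21 (adjusted p = 0.0101), a call lost without the 9 libraries with acinar transcripts. Of 4 adipocyte markers 1, Plin4, rose in females (1 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation), a call lost without replicate 5 of the 6-month or 3 or 8 of the 22-month females. Of 12 Kupffer cell markers 1, Folr2, was higher in females at 22 months (0 adjusted over the list alone, adjusted p = 0.930 with an estimated correlation). That call was lost without replicate 5 or 6 of the 22-month females or 4, 5, 7 or 8 of the 22-month males (adjusted p up to 0.1303) and in 4 of 13 settings, and 6 members were called without replicate 2 of the 22-month males. Of 18 oxidative phosphorylation genes 1, Atp5b, fell in males (7 lower adjusted over the list alone, adjusted p = 0.366 with an estimated correlation). That call was lost in 14 of 34 fits without 1 library, those without replicate 1, 2, 4, 5, 6, 7 or 8 of the 6-month males or 2, 3, 4, 5, 6, 7 or 8 of the 22-month males. Over the 34 fits without 1 library the count of the list ran from 0 to 5. The call of Atp5b was also lost in 5 of 13 settings. Of 10 immediate-early genes 1, Jun, was lower in females at 6 months (0 adjusted over the list alone, adjusted p = 0.933 with an estimated correlation). That call was lost without replicate 1, 3, 4, 6 or 8 of the 6-month females, 2, 4 or 5 of the 6-month males or 2 or 3 of the 22-month females, and in 8 of 13 settings. Stellate cell, endothelial, cell cycle and pancreatic acinar lists held 58 tested members and 0 edgeR calls in 290 tests, with 13 at an unadjusted p under 0.05 and 7 calls by DESeq2.

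Removing random libraries, as many per group as had acinar transcripts, gave 286 to 1116 calls for age in males over 30 draws (median 516.5), against 361 without the 9 libraries, and 3 draws gave 361 or fewer. For age in females the draws gave 295 to 1643 calls (median 803.5), against 877.

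A hypothesis was that sex-biased genes of males move toward the female level with age, taking genes with a log2 difference of at least 1 between the sexes at 6 months. Over 100 random splits of the 6-month males into a part that chose the genes and a part that measured them, 60.9% of a mean of 963 genes did so (range 54.4 to 66.1), and 95% of regroupings of age lay under 63.1. A second hypothesis was that those of females move away from the male level, which 63.4% of a mean of 951 genes did (range 55.8 to 75.8), with 95% of regroupings under 65.6. Neither mean share exceeded its limit, so neither predicted move was shown. The limit comes from single regroupings, which vary more than a mean over 100 splits. The comparison is thus of unlike values and cannot decide, and both hypotheses stay open.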
